A study of Mus musculus with 12 samples.

How the data were processed

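Vascular smooth muscle cells (VSMC) from the aorta of C57BL/6 mice were studied with RNA sequencing after silencing of Thoc5 and with sequencing of RNA that coprecipitated with Thoc2 or Thoc5 (RIP-seq). Thoc2 and Thoc5 are subunits of the THO complex, which couples transcription to the export of mRNA from the nucleus. The 12 samples comprised 2 libraries with a non-targeting short hairpin RNA (shNT), 2 libraries with a hairpin against Thoc5 (shThoc5), 6 RIP-seq libraries and 2 chromatin immunoprecipitation libraries. The RNA-seq cells were at passages 4 to 8 and were collected 4 days after infection, per the labels. The RIP-seq libraries were an input, a Thoc2 immunoprecipitate and a Thoc5 immunoprecipitate at passage 3 and again at passage 10, with 1 library of each. The 2 chromatin immunoprecipitation libraries were not analysed here.

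Per the submitters' processing notes, reads were handled with bcl2fastq, Subread, featureCounts, limma, MACS2 2.1.1 and HOMER 4.8.3 on the mm9 build. Which of these tools served which file is not given in the sources used here. The deposited RNA-seq table holds read counts per gene for the 4 libraries, and counts by gene were not normalized. A further deposited table holds the authors' own comparison of shThoc5 with shNT, with a log2 fold change, a p-value and an adjusted p-value per gene and a gene length, per the file headers. The deposited RIP-seq tables hold, for each antibody and passage, the read counts of the input and the immunoprecipitate and a normalized signal. That signal equalled the count times a single factor, the same for both libraries of a table. They also hold the authors' ratio of immunoprecipitate to input, which equalled the quotient of the normalized values after 2 was added to each. For selected genes the authors deposited a score per gene, the posterior probability of an enriched class, which was at least 0.3. The RIP-seq tables list only genes with at least 11 reads over input and immunoprecipitate, so a gene left out had at most 10 reads. Such genes were left out of the comparisons of immunoprecipitate with input. In the list medians that compare the inputs of passage 10 and passage 3, where 691 of 13459 genes were unlisted at passage 10 and 185 at passage 3, they entered as 0 reads, and medians with them at 10 reads are given beside. Input counts were the same in both tables of a passage. The table that gives the genes shared by both antibodies at passage 10 has column headings shifted by a column, and its values were matched to the tables of the single antibodies.

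Gene identifiers were matched to symbols with a RefSeq table for GRCm38.p6, used only for names and for genes whose spans overlap. RNA-seq covered 26301 identifiers, of which 24191 matched, and RIP-seq covered 15352, of which 14732 matched. Strand use in counting is not given in the sources used here, so named genes whose spans overlap those of other counted genes are reported as uncertain.

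Counts per gene were compared between shThoc5 and shNT with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test after TMM scaling and filterByExpr, with Benjamini-Hochberg adjustment and a threshold of 0.05. Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), other scaling factors, other low count filters, a test against a fold of 1.5, a model with the replicate number as a term, and the omission of each library in turn. In an omission the lone library of a group was assumed to vary like the other group. The 20 gene lists, the enrichment rule and the rule for named genes were fixed before the data were examined. The lists were tested with camera at a preset correlation of 0.01 between genes, with fry and an estimated correlation beside it, for lists with at least 5 tested members. They covered contractile genes, smooth muscle regulators, extracellular matrix, proliferation, p53 targets, inflammatory, interferon-stimulated and immediate early genes, THO and mRNA export, unfolded protein and amino acid stress, heat shock and cholesterol synthesis. Further lists held markers of chondrocytes and bone, macrophages, endothelium, adventitial fibroblasts, adipocytes and mesothelium or epithelium, and the ribosomal protein and nuclear respiratory chain genes. Nothing in the labels says that the libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. With 2 libraries against 2, an exact permutation test cannot give a two-sided p below 0.333.

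RIP-seq counts were scaled to CPM with each library's total as the denominator. Enrichment was the log2 ratio of immunoprecipitate to input CPM with 0.5 CPM added to both. A gene was called enriched at a log2 ratio of at least 1 with at least 10 reads and at least 1 CPM in the immunoprecipitate. With 1 library per antibody and passage there was no replicate check and no p-value, and the 95% intervals given for single genes are exact intervals that cover counting error only. Each list's median was ranked among the medians of 10000 random lists of the same size matched on mean expression, as a description of these libraries. Overlaps were set against the product of the list sizes over the number of genes measured in both. They were also set against 100 simulations of unchanged libraries that share an input, with counting noise only. Alternatives were added amounts of 0.1 and 1 CPM, TMM factors, a minimum of 50 reads and enrichment thresholds of 1.5-fold and 4-fold. Library totals without ribosomal RNA, unlisted genes set at 10 reads, changed list members and the omission of an immunoprecipitate were alternatives chosen after seeing the data.

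Named genes from RNA-seq were Thoc5 and the other THO subunits, up to 12 genes with the largest change in each direction among those past the threshold with a mean log2 CPM of at least 4, and up to 4 members of each list with the smallest p. Because edgeR called no gene, the second part of that rule was applied to the DESeq2 calls, an extension chosen after the values were seen. Named genes from RIP-seq were the 8 most enriched genes of each immunoprecipitate with at least 50 reads, contractile genes called enriched, and the 6 largest rises and falls between passages. Predicted genes, ribosomal RNA and pseudogenes were passed over, and 1 gene that the rule takes is not reported here. Members of the lists given as examples for the inputs, and for THO and mRNA export in RIP-seq, were chosen after their values were seen.

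The computations were tested on simulated data. With 13569 genes drawn at the spread of the shThoc5 and shNT libraries and 50 genes changed at each size, edgeR recovered 8% of 1.5-fold, 26% of 2-fold, 88% of 4-fold and 100% of 8-fold changes. It also called 16 unchanged genes. DESeq2 recovered 20%, 54%, 92% and 100% and called 33 unchanged genes. Each gene was drawn independently, without the difference between replicate numbers seen in the data, so these rates may not hold there. In the data edgeR gave Thoc5, at a log2 fold change of −2.51, an adjusted p of 0.499. Of 200 null lists 5 had a camera p under 0.05. These genes were drawn without correlation between them, so this does not check camera on lists whose genes vary together. The estimated correlation was 0.192 for the matrix list and 0.37 for the endothelial list. In simulated immunoprecipitates the enrichment rule called 97.5% to 99.0% of genes at 3-fold, 100% at 6-fold and at most 3 of 14752 unchanged genes. These libraries held counting noise only, and genes lowest in the input were not among those changed. The rates therefore do not cover spread between real libraries beyond counting noise. Python 3.11.15 with numpy, scipy, pandas and matplotlib was used for RIP-seq.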

Results

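The RNA-seq libraries held 18498200 and 21037732 counted reads for shNT and 20206296 and 15819207 for shThoc5. In each of the 4 the most abundant transcript was Fn1, which encodes fibronectin. The passage 3 RIP-seq libraries held 36336141 reads for the input, 5396291 for Thoc2 and 5975866 for Thoc5. The passage 10 libraries held 19038973, 16303503 and 9364965 reads. Ribosomal RNA made up 0.962% of the passage 3 input, 18.0% of the Thoc2 and 6.74% of the Thoc5 immunoprecipitate. At passage 10 these shares were 0.718%, 0.873% and 1.60%. Replicate libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of 48.1 for shNT and 45.4 for shThoc5.

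The first comparison asked which transcripts differed after silencing of Thoc5. The labels of both silenced libraries bear the same number beside the name Thoc5, and no other hairpin against it is among the samples. Effects of that hairpin on other targets cannot be told apart from those of Thoc5 loss. Thoc5 itself stood at 36.9 ± 4.62 CPM in shNT and 6.45 ± 1.12 CPM in shThoc5 (mean ± SD, n = 2), lower in both silenced libraries. Its log2 fold change was −2.51 with a standard error of 0.208. The edgeR quasi-likelihood test gave an adjusted p of 0.499 for it over all genes and 0.000882 adjusted over the list alone of THO and mRNA export genes, and DESeq2 gave 1.547e-14 over all genes. Without shThoc5 replicate 1 the edgeR adjusted p was 0.0152, and with no low count filter it was 0.0156. Other THO subunits showed log2 fold changes of 0.36 (Thoc3), 0.22 (Thoc6), 0.12 (Thoc1), 0.10 (Thoc7) and −0.03 (Thoc2), none past the threshold. The spans of Thoc1, Thoc6 and Thoc7 overlap those of Usp14, Hcfc1r1 and Atxn7, so their reads are uncertain. Thoc2 stood at 140 ± 16.1 CPM in shNT and 138 ± 16.03 CPM in shThoc5.

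Of the genes that DESeq2 called lower after Thoc5 silencing, Sgms2, a sphingomyelin synthase, fell by 1.57 on the log2 scale (adjusted p = 0.00322 by DESeq2), and Prkcsh, a subunit of glucosidase II of the endoplasmic reticulum, fell by 1.56, from 152 ± 25.9 to 51.6 ± 18.0 CPM. Crip2, a LIM domain protein, had a log2 fold change of −1.45 in DESeq2 and −1.44 in the authors' deposited table. Cdh5, the endothelial cadherin, fell from 114 ± 13.2 to 46.7 ± 9.02 CPM (log2 −1.29, adjusted p = 9.047e-05 by DESeq2). Esyt1, which tethers endoplasmic reticulum to the plasma membrane, fell from 154 ± 18.1 to 65.0 ± 1.95 CPM (log2 −1.25, adjusted p = 2.44e-06 by DESeq2). Mfap3, Aspn, Vangl1, Rbm42 and Dcbld2 had log2 fold changes between −1.27 and −1.21. The spans of Mfap3, Aspn and Dcbld2 overlap those of Fam114a2, Cenpp and St3gal6, so their reads are uncertain.

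Genes called higher by DESeq2 included Lats2, a kinase of the Hippo pathway, which rose from 124 ± 4.35 to 230 ± 51.8 CPM (log2 0.90). Pkdcc, a secreted kinase, rose from 36.7 ± 8.96 to 78.1 ± 9.69 CPM (log2 1.09), and Jade2 from 28.2 ± 3.03 to 58.2 ± 6.26 CPM (log2 1.05). Hnrnpf, an RNA-binding protein that takes part in splicing, rose by 0.91 on the log2 scale, and Mgat4b, a glycosyltransferase, by 0.97. Tmem184c, Pgm1, Parvb, Arhgef7 and Glipr2 had log2 fold changes between 0.73 and 0.88. In all, DESeq2 called 47 genes, 12 higher and 35 lower, and gave no adjusted p for 3157.

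The edgeR test called 0 of 13569 genes, with 651 at an unadjusted p under 0.05 where chance gives 678. Limma-voom called 0 genes, with 646 at an unadjusted p under 0.05. The authors' deposited table also held 0 genes at an adjusted p under 0.05, with a lowest adjusted p of 0.9999 and 178 of 12371 genes at an unadjusted p under 0.05. Without shThoc5 replicate 1, edgeR called 47 genes, of which 16 were among the 47 of DESeq2, and with no low count filter it called 1.

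**Figure D1:**
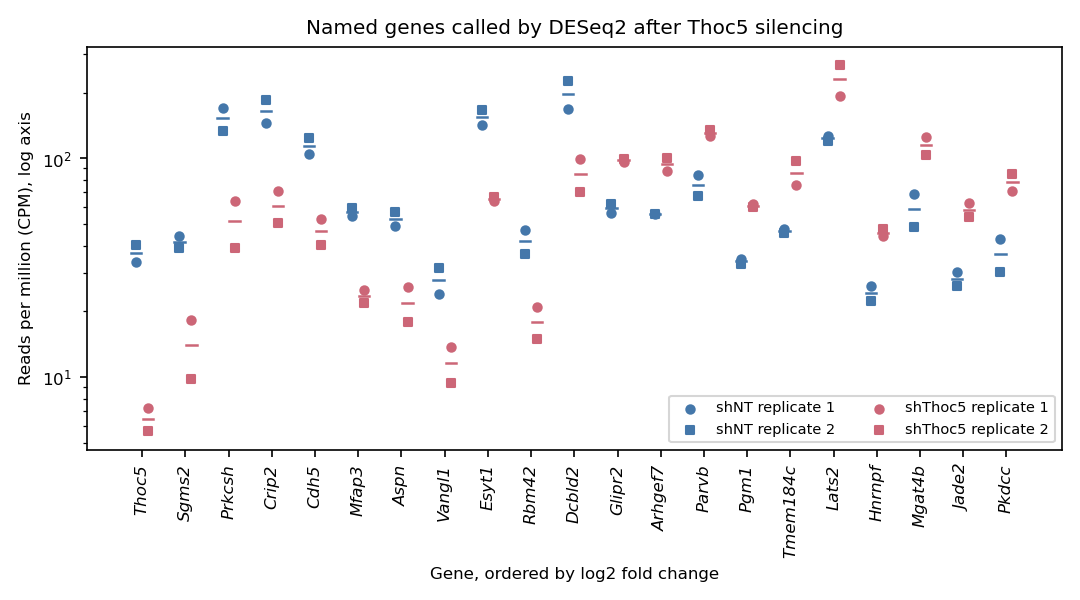
CPM on a log axis of Thoc5 and the other genes named here that DESeq2 called, for shNT (blue) and shThoc5 (red), with circles for replicate 1, squares for replicate 2 and a bar for the mean. Thoc5 lies at a mean of 36.9 CPM in shNT and 6.45 CPM in shThoc5.

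Extracellular matrix genes were lower after Thoc5 silencing, with a median log2 fold change of −0.24 over 32 members (camera adjusted p = 0.00129, and adjusted p = 0.632 with an estimated correlation). In both silenced libraries 10 members were lower than in both shNT libraries and 1 was higher, where chance separates the groups, in either direction, for 33.3% of genes. Decorin (Dcn) stood at 564 ± 26.4 CPM in shNT and 294 ± 10.7 CPM in shThoc5, osteonectin (Sparc) at 4619 ± 574 and 2229 ± 859 CPM, and the collagen gene Col3a1 at 2389 ± 118 and 1682 ± 195 CPM. Endothelial markers were lower too (median −0.32 over 9 members, camera adjusted p = 0.0103, and adjusted p = 0.632 with an estimated correlation), with 5 members lower in both silenced libraries and 0 higher. Beside Cdh5, Emcn stood at 251 ± 147 and 131 ± 18.5 CPM and Pecam1 at 120 ± 0.00774 and 96.4 ± 9.26 CPM. The unfolded protein and amino acid stress list was also lower (median −0.25 over 17 members, camera adjusted p = 0.0161, and adjusted p = 0.632 with an estimated correlation). Its members included the chaperone Hspa5, whose span overlaps that of Rabepk, at 857 ± 5.88 and 633 ± 97.0 CPM, the amino acid enzyme Asns, at 37.5 ± 5.31 and 26.8 ± 6.10 CPM, and Trib3, at 15.7 ± 4.00 and 10.7 ± 1.82 CPM. In that list 4 members were lower in both and 1 was higher.

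For each of these 3 lists fry gave an adjusted p of 0.916. In edgeR, 1 gene passed adjusted over the list alone in the matrix list (Dcn, adjusted p = 0.0389), 1 in the endothelial list (Cdh5, 0.00714) and 1 in the THO list (Thoc5). No member of the other lists passed adjusted over the list alone. The calls of these 3 lists depended on single libraries, while their medians stayed below 0 in each omission. A first component with 61.3% of the variance separated the replicate numbers, which each omission left unequal between the groups. The matrix list had a camera adjusted p of 0.156 without shNT replicate 1 (median −0.15) and 0.311 without shThoc5 replicate 2 (median −0.048). The endothelial list had 0.372 without shNT replicate 2 (median −0.056), and the stress list had 0.0604 without shThoc5 replicate 2 (median −0.17).

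The contractile list, with a median of −0.11 over 25 members, did not pass the threshold (camera adjusted p = 0.107). The actin gene Acta2 stood at 1873 ± 899 CPM in shNT and 973 ± 266 CPM in shThoc5. Mylk, the kinase of myosin light chain, stood at 46.2 ± 3.56 and 67.9 ± 13.2 CPM, with a span that overlaps the non-coding RNA E130310I04Rik, so its reads are uncertain. The list median was 0.13 without shNT replicate 2 and 0.07 without shThoc5 replicate 1. It was −0.49 without shNT replicate 1 (adjusted p = 1.22e-05) and −0.28 without shThoc5 replicate 2 (adjusted p = 6.81e-06). Smooth muscle regulators had a median of −0.13 (adjusted p = 0.13), which was −0.048 without shNT replicate 2 and −0.075 without shThoc5 replicate 2, with Notch3 at 145 ± 6.51 and 195 ± 46.7 CPM and Klf4 at 117 ± 4.35 and 91.8 ± 13.6 CPM. Proliferation genes had a median of 0.17 (camera adjusted p = 0.153), which was −0.77 without shThoc5 replicate 1 and 1.00 without shThoc5 replicate 2. It was −0.48 without shNT replicate 2 and 0.75 without shNT replicate 1. Each omission left the replicate numbers unequal between the groups, so a turned direction cannot be told apart from the difference between the numbers. Cholesterol synthesis genes had a median of −0.24 (adjusted p = 0.057), with Srebf2 at 159 ± 22.3 and 129 ± 5.12 CPM. It was 0.34 without shNT replicate 2 (adjusted p = 0.00446) and −0.79 without shNT replicate 1 (adjusted p = 4.4e-14), and −0.40 without shThoc5 replicate 2 (adjusted p = 4.35e-05). The p53 target list had a median of 0.16 (adjusted p = 0.0516), with Sesn1 at 57.6 ± 0.496 and 76.4 ± 4.34 CPM, and passed without shNT replicate 2 (0.0104) and without shThoc5 replicate 1 (3.54e-05). Without shThoc5 replicate 2 its direction turned (−0.01). The p53 and cholesterol lists passed the threshold with no low count filter, both at an adjusted p of 0.0412, and with library totals, at 0.0429 and 0.0331.

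Inflammatory genes had a median of 0.17 (camera adjusted p = 0.057) and immediate early genes a median of 0.30 (0.0657), with Fos at 5.79 ± 1.59 and 10.7 ± 2.75 CPM. The remaining adjusted p-values from camera were 0.0828 for ribosomal proteins (median −0.06), 0.122 for interferon-stimulated genes (−0.13), 0.153 for adventitial fibroblast markers (−0.34) and 0.155 for adipocyte markers (−0.26). They were 0.345 for chondrocyte and bone markers (−0.26), 0.783 for heat shock genes (0.07, with a mean of −0.01) and 0.802 for macrophage markers (−0.14). The THO and mRNA export list (0.802) had a median of 0.04 and a mean of −0.06, and the nuclear respiratory chain list (0.88) tested as lower with a median of 0.01. Mesothelial and epithelial markers had too few tested members.

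Single libraries also moved these remaining lists, again with the replicate numbers left unequal between the groups. Inflammatory and immediate early genes passed without shNT replicate 2 (camera adjusted p = 0.00446 for both) and without shThoc5 replicate 1 (0.00424 and 0.000145). The inflammatory median was 0.090 without shNT replicate 1 and 0.081 without shThoc5 replicate 2. The immediate early median was 0.059 without shNT replicate 1 and −0.043 without shThoc5 replicate 2, where camera still tested it as higher. Adventitial fibroblast markers passed without the same libraries (0.0344 and 0.00424). Adipocyte markers passed without shNT replicate 1 (5.97e-07) and without shThoc5 replicate 1 (0.0038), chondrocyte and bone markers without shThoc5 replicate 1 (0.0493) and ribosomal proteins without shThoc5 replicate 2 (0.000239). The direction turned for macrophage, chondrocyte and adipocyte markers without shThoc5 replicate 2, with medians of 0.17, 0.07 and 0.11. It also turned for THO and heat shock genes without shNT replicate 1 and without shThoc5 replicate 2, and for adipocyte markers and the respiratory chain without shNT replicate 2. The respiratory chain turned as well without shThoc5 replicate 1.

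The RIP-seq comparison asked which transcripts were recovered with Thoc2 and Thoc5. At passage 3 the most enriched named transcripts with Thoc2, ranked by the ratio with 0.5 CPM added, were the vault RNA Vaultrc5 and Myh6, the cardiac myosin heavy chain. Vaultrc5 had 647 reads against 20 in the input, 218-fold by CPM (95% interval 140 to 359), and Myh6 had 351 reads against 11, 215-fold (119 to 434). Zbed6, which lies inside the span of Zc3h11a, and Lars2, Rest, Malat1, Syne2 and Lyst followed, with log2 enrichments from 5.95 to 5.27. The log2 enrichment of Lars2 differed by at most 0.171 from that of 28S ribosomal RNA in the 4 immunoprecipitates. With Thoc5 at passage 3 the nuclear long non-coding RNA Malat1 led by that ratio, at 28.9-fold without the added amount (27.5 to 30.4). The imprinted gene Peg3 had 70 reads against 0 in the input. The non-coding RNA Meg3 was at 24.2-fold (22.5 to 26.0), Firre at 21.7-fold (17.8 to 26.7), and Sned1, Lyst, Tspoap1 and Ccdc88b were at log2 enrichments from 4.44 to 4.10. Without the added amount Tspoap1 (50.0-fold, 24.96 to 113.6), Lyst (32.4-fold, 20.99 to 51.8) and Peg3, with 0 input reads, lay above Malat1. The spans of Myh6, Meg3 and Peg3 overlap those of Cmtm5, Rtl1 and the antisense RNA Peg3os, so their reads are uncertain.

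By the ratio with 0.5 CPM added, the Thoc2 immunoprecipitate of passage 10 was led by Firre at 23.8-fold (19.9 to 28.7), Syne2 at 16.9-fold (15.1 to 19.0) and Kmt2d, a histone methyltransferase, at 13.1-fold (12.4 to 13.9). Syne2 and Syne1 encode giant proteins of the nuclear envelope. Cit, Helz2, Tet2, Syne1 and Alpk1 followed at log2 enrichments from 3.70 to 3.43. With Thoc5 the same 3 genes led by that ratio, Syne2 at 6.68-fold (5.88 to 7.60), Kmt2d at 5.48-fold (5.13 to 5.85) and Firre at 5.65-fold (4.59 to 6.98). Vps13c, Alpk1, Polq, Tet2 and Fgd3 followed at 2.27 to 2.13 on the log2 scale. Without the added amount Cit (15.0-fold) and Tet2 (13.3-fold) lay above Kmt2d with Thoc2, and Polq (5.55-fold) lay above Kmt2d with Thoc5, inside the counting intervals.

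Of the detected members of the contractile list, 7 of 27 were enriched with Thoc2 and 4 of 25 with Thoc5 at passage 3. The shares of all detected genes were 19.8% and 24.6%. At passage 10 the enriched members were 4 of 24 and 2 of 25, against 12.6% and 6.12% of all detected genes. The list's share lay below that of all genes with Thoc5 at passage 3 and above it in the other immunoprecipitates, which was not tested. Of the contractile genes, Flna, which encodes filamin A, and Ppp1r12b, a subunit of myosin phosphatase, were enriched in all 4 immunoprecipitates. The log2 enrichments of Flna were 2.45 (Thoc2) and 2.26 (Thoc5) at passage 3 and 1.94 and 1.12 at passage 10, and those of Ppp1r12b were 3.66, 3.81, 1.73 and 1.94. Myh11, the smooth muscle myosin heavy chain, was enriched with Thoc2 at both passages, at 1.58 and 1.07. Smtn was enriched at passage 3 with Thoc2 (1.097) and Thoc5 (1.30), Mylk, whose span overlaps E130310I04Rik, at passage 10 with Thoc2 (1.70) and Synpo2 at passage 3 with Thoc2 (1.67). Pln, with 52 reads against 3 in the input, was 117-fold higher with Thoc2 at passage 3 (37.8 to 584), with a span that overlaps Cep85l, and Casq2 was at 1.13 with Thoc2 and 1.101 with Thoc5. The median of the contractile list at passage 3 with Thoc2 was 0.25, higher than that of 95.7% of random lists. It was −0.16 without the 8 members that heart muscle also expresses. Its median was −0.09 with Thoc5 at passage 3 and −0.38 and −0.13 at passage 10 with Thoc2 and Thoc5.

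Of the detected members of the THO and mRNA export list, 3 of 23 (13.0%) were enriched with Thoc2 and 7 of 23 (30.4%) with Thoc5 at passage 3, where 19.8% and 24.6% of all detected genes were. At passage 10 they were 3 of 24 (12.5%) and 1 of 24 (4.17%), where the shares of all detected genes were 12.6% and 6.12%. Mcm3ap, which encodes the scaffold of another export complex, was enriched in all 4 immunoprecipitates, with log2 values of 2.26 (Thoc2) and 1.96 (Thoc5) at passage 3 and 2.11 and 1.12 at passage 10. The Thoc2 transcript was enriched in 3, at 1.52 and 1.26 at passage 3 and 1.14 with Thoc2 at passage 10, and stood at −0.18 with Thoc5 at passage 10. Zc3h11a was also enriched in 3, at 2.13, 1.72 and 1.73, and stood at 0.78 with Thoc5 at passage 10. The Thoc5 transcript lay between 0.29 and 0.84 and was not called enriched in any of the 4. The spans of Mcm3ap and Zc3h11a overlap those of Ybey and Zbed6, so their reads are uncertain.

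By the enrichment rule, 2354 of 11889 detected genes (19.8%) were enriched with Thoc2 and 3069 of 12461 (24.6%) with Thoc5 at passage 3. At passage 10 the counts were 1549 of 12312 (12.6%) and 749 of 12247 (6.12%). The median fold of the enriched genes was 3.05, 2.93, 2.69 and 2.33 in the same order. The authors' deposited lists held 1046, 919, 2277 and 560 genes, of which 92.7%, 95.3%, 68.0% and 88.0% were also enriched here. The cutoffs differ, since the lowest ratio in those lists, corrected for depth, was 3.87, 4.68, 1.78 and 2.32, against 2-fold here. For Thoc2 at passage 10 all 1549 genes called here were in the authors' list. Both selections rest on the same counts, so their agreement is not independent support. The counts moved by more than 1.5 times with other enrichment thresholds. No control immunoprecipitate was among the libraries.

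Thoc2 and Thoc5 were compared over the genes detected with both. At passage 3 they shared 1617 enriched genes, of 2124 with Thoc2 and 2547 with Thoc5, where independent lists would share 475 and simulated unchanged libraries with a common input shared 0.09 on average. That was 76.1% of the smaller list. At passage 10 they shared 596, of 1482 with Thoc2 and 689 with Thoc5, against 85.4 and 0.12, or 86.5% of the smaller list. Enrichments of the 2 proteins correlated across genes, which are not independent replicates, with Spearman's rho of 0.828 at passage 3 and 0.862 at passage 10. The covariance was 1.02 at passage 3, where simulated counting noise with a shared input gave 0.00553, and 0.410 at passage 10, where it gave 0.00867. Part of the excess may come from the shared input library. In the authors' deposited lists 425 genes were shared at passage 3 and 455 at passage 10.

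**Figure D2:**
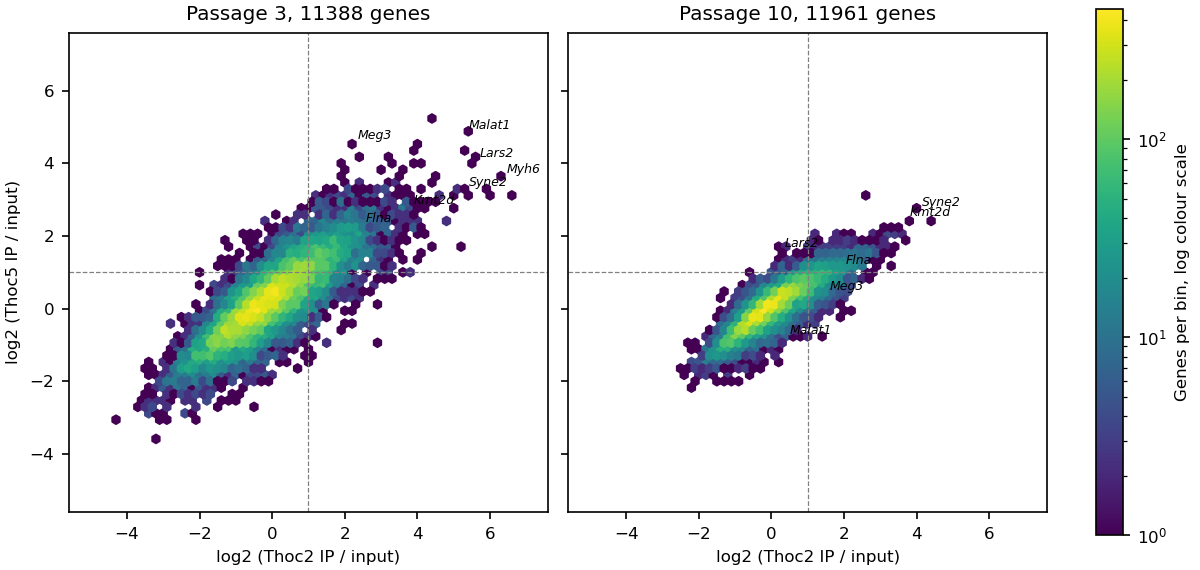
Log2 ratio of immunoprecipitate to input for Thoc2 (horizontal axis) and Thoc5 (vertical axis) over 11388 genes at passage 3 and 11961 genes at passage 10, coloured by the number of genes per bin on a log colour scale. Dashed lines mark the enrichment threshold of 1, and Malat1 lies at 5.31 and 4.84 at passage 3 and at 0.39 and −0.82 at passage 10.

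Long genes were recovered more than short genes with both proteins and at both passages. The rank correlation of enrichment with the deposited gene length across genes was 0.567 (Thoc2) and 0.416 (Thoc5) at passage 3 and 0.618 and 0.584 at passage 10. In the shortest quintile of genes the median log2 ratio was −1.11, −0.56, −0.66 and −0.48 in that order, and in the longest quintile it was 0.89, 0.74, 0.73 and 0.52. A length was known for 81.5% to 88.4% of the enriched genes.

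**Figure D3:**
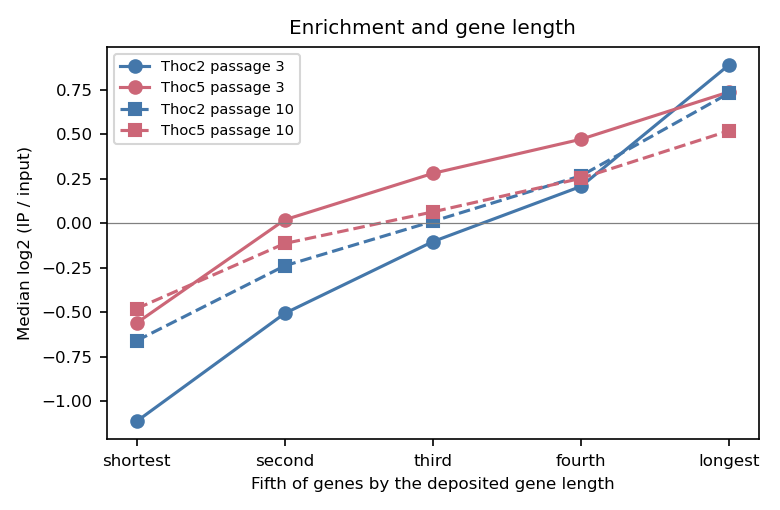
Median log2 ratio of immunoprecipitate to input for each quintile of genes by deposited gene length, for Thoc2 (blue) and Thoc5 (red) at passage 3 (solid lines, circles) and passage 10 (dashed lines, squares). Each line climbs from the shortest quintile, between −1.11 and −0.48, to the longest quintile, between 0.52 and 0.89.

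Ribosomal protein transcripts were the list with the lowest median in each immunoprecipitate, at −2.01 (Thoc2) and −1.40 (Thoc5) at passage 3 and −1.10 and −0.98 at passage 10. Nuclear transcripts of the respiratory chain followed at −1.74, −1.28, −1.06 and −0.88. None of 10000 random lists had a median as low for either list. After removal of the length trend the medians were −0.66, −0.57, −0.27 and −0.32 for ribosomal proteins and −0.44, −0.41, −0.22 and −0.16 for the respiratory chain.

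With Thoc2 at passage 3, the inflammatory (−1.14) and macrophage (−0.99) lists were lower than all but 0.31% and 0.35% of random lists. With Thoc5 at passage 3 the adventitial fibroblast list (−0.63) was at percentile 1.63, and with Thoc2 at passage 10 the macrophage list (−0.74) was at 0.98. With Thoc5 at passage 10 smooth muscle regulators (0.46) were at percentile 99.9, the matrix list (0.27) at 98.9 and the THO and mRNA export list (−0.21) at 1.94. The random lists were not matched on gene length. After removal of the length trend, over members with a known length, these Thoc5 medians at passage 10 were 0.13, −0.04 and 0.07. The inflammatory median with Thoc2 at passage 3 was then −0.56, and the adventitial fibroblast median with Thoc5 at passage 3 was −0.32. The other list medians in the 4 immunoprecipitates lay between −0.87 and 0.54, inside the central 95% of their random lists. TMM factors moved the median of all genes with Thoc5 at passage 3 from 0.20 to −0.04, and library totals without ribosomal RNA moved that with Thoc2 at passage 3 from −0.14 to 0.12. The list medians that changed sign with TMM factors lay between −0.06 and 0.20.

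Enrichment was then compared between passage 10 and passage 3. Malat1 showed the largest difference with Thoc5, at 4.84 at passage 3 and −0.82 at passage 10, and a large one with Thoc2, at 5.31 and 0.39. Lars2 with Thoc2 stood at 5.61 and 0.26. Meg3 with Thoc5 stood at 4.57 and 0.41, and Crebbp, a histone acetyltransferase, with Thoc2 at 5.08 and 1.96. Tnnt2, Hirip3 and Arhgap5 had differences of −3.14 to −2.96 with Thoc2, and Uba7, Echdc2, Ccnl2 and Srek1 with Thoc5 had differences of −3.09 to −2.85. In the other direction Mylk with Thoc2 stood at −0.56 at passage 3 and 1.70 at passage 10, and the respiratory chain transcript Ndufb6 at −3.37 and −1.16. Cand2, Map3k12, Agbl5 and Polr2b with Thoc2 differed by 3.49 to 2.39, and Zbtb33, Cand2, Rpe, Agbl5, Slc25a32 and Dr1 with Thoc5 by 2.52 to 1.79. The spans of Mylk, Cand2, Polr2b, Agbl5, Map3k12, Hirip3, Rpe and Zbtb33 overlap those of other genes, such as Rpl32 for Cand2 and Igfbp7 for Polr2b, so their values are uncertain.

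Enriched genes were then compared across passages. Thoc2 shared 1192 enriched genes between passages, of 2080 at passage 3 and 1420 at passage 10 (83.9% of the smaller list), where independent lists would share 269.6, and Thoc5 shared 531, of 2473 and 636 (83.5%), against 141.3. All 4 immunoprecipitates shared 439 of 10506 genes, against 2.91 for independent lists, and the 3 without the passage 3 Thoc2 immunoprecipitate shared 483 of 11004, against 17.0. The lists were not independent, since both proteins had the same input at each passage and enrichment rose with gene length in all 4. In the authors' deposited lists 685 genes were shared by Thoc2 and 180 by Thoc5 across passages. The ribosomal protein list was less depleted at passage 10, by a median of 0.96 with Thoc2 and 0.46 with Thoc5, and so was the respiratory chain list, by 0.75 and 0.35, where the medians of all genes were 0.14 and −0.12. Passage could not be separated from the preparation of the cells and libraries.

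The genes enriched in RIP-seq were then followed in the RNA-seq libraries, to ask whether transcripts recovered with Thoc2 or Thoc5 differed after Thoc5 silencing. The sets of 2201 and 2730 tested genes from Thoc2 and Thoc5 at passage 3 had median log2 fold changes of 0.04 and 0.05. The sets of 1498 and 699 genes from passage 10 had medians of 0.05 and 0.03, and the median of all genes was 0.01. Camera gave adjusted p-values of 0.276, 0.167, 0.167 and 0.298, so none passed the threshold. The authors' deposited lists gave adjusted p-values from 0.161 to 0.394. Fold changes after silencing had a rank correlation of 0.0261 with gene length across genes.

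The inputs of passage 10 and passage 3 were compared as the background of the immunoprecipitates. Interferon-stimulated and inflammatory transcripts were far lower at passage 10, and cell cycle and cholesterol synthesis transcripts were higher. The interferon-stimulated list had a median log2 ratio of −4.75 with unlisted genes at 0 reads, or −4.56 with them at 10 reads, with 21 of 22 members at −1 or below. Ifit1, whose span overlaps that of Ifit1bl1, stood at 1440 CPM at passage 3 and 16.3 CPM at passage 10, and Ifi44 at 207 and 1.05 CPM. The inflammatory list had a median of −3.00 (−2.50 with unlisted genes at 10 reads), with Il6, whose span overlaps that of A230098N10Rik, at 847 and 3.05 CPM and Ptgs2 at 1626 and 20.1 CPM, whereas Cxcl12 stood at 2045 and 9006 CPM. Immediate early genes had a median of −1.31 and p53 targets of −0.68, with the cell cycle inhibitor Cdkn1a at 1028 and 103.5 CPM.

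Proliferation genes had a median of 2.15 at passage 10 over passage 3, with 23 of 32 members at 1 or above. The kinase gene Aurkb was 12.9-fold higher (95% interval 9.97 to 16.9) and Birc5 9.72-fold (8.12 to 11.7). Cholesterol synthesis genes had a median of 1.94 (1.74 with unlisted genes at 10 reads), with Srebf2 12.6-fold (11.5 to 13.8) higher. The contractile list had a median of 0.66 over members that went both ways. Acta2 stood at 2091 and 4549 CPM and the integrin gene Itga8, whose span overlaps the non-coding RNA E030013I19Rik, at 2.34 and 30.4 CPM, while Mustn1 stood at 320 and 15.0 CPM and desmin (Des) at 9.44 and 0.893 CPM. The spans of Srebf2 and Des overlap those of Mir33 and Gm15179, so their reads are uncertain. Smooth muscle regulators had a median of 0.46 and the THO and mRNA export list of 0.63. The matrix list had a median of −0.29, with elastin (Eln) at 30.3 and 1483 CPM, Dcn at 1041 and 13.8 CPM and the metalloproteinase gene Mmp3 at 700.3 and 7.67 CPM.

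Markers of other cell types moved as well. Macrophage markers, of which 11 of 17 were unlisted at passage 10, had a median of −3.02 with unlisted genes at 10 reads, the most they can have had. With these at 0 reads the median was set by the added amount, at −3.38 with 0.5 CPM and −5.59 with 0.1 CPM. Csf1r stood at 36.4 and 4.04 CPM. Endothelial markers had a median of −2.15 (−2.08 with unlisted genes at 10 reads), with Emcn at 76.1 and 9.87 CPM, and adventitial fibroblast markers of −1.71, with Ly6a at 1491 and 90.03 CPM. Chondrocyte and bone markers had a median of 1.61, with Col2a1 25.1-fold (20.4 to 31.2) and Acan 17.1-fold (12.4 to 24.2) higher at passage 10. Mesothelial and epithelial markers had a median of 1.096 (0.80 with unlisted genes at 10 reads) and adipocyte markers of −0.22. The stress list stood at −0.34. The median of all genes was 0.43, a shift that TMM factors removed. Heat shock (0.20), ribosomal protein (0.35) and respiratory chain (0.38) lists lay near that shift and changed sign with TMM factors, to −0.23, −0.09 and −0.05. With these factors the medians were 0.015 for smooth muscle regulators, 0.19 for THO and mRNA export and 0.22 for contractile genes. They were −0.65 for adipocyte markers, −0.67 for the matrix, −0.77 for stress and −1.12 for p53 targets. Each passage had 1 input library, so these values compare libraries.

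**Figure D4:**
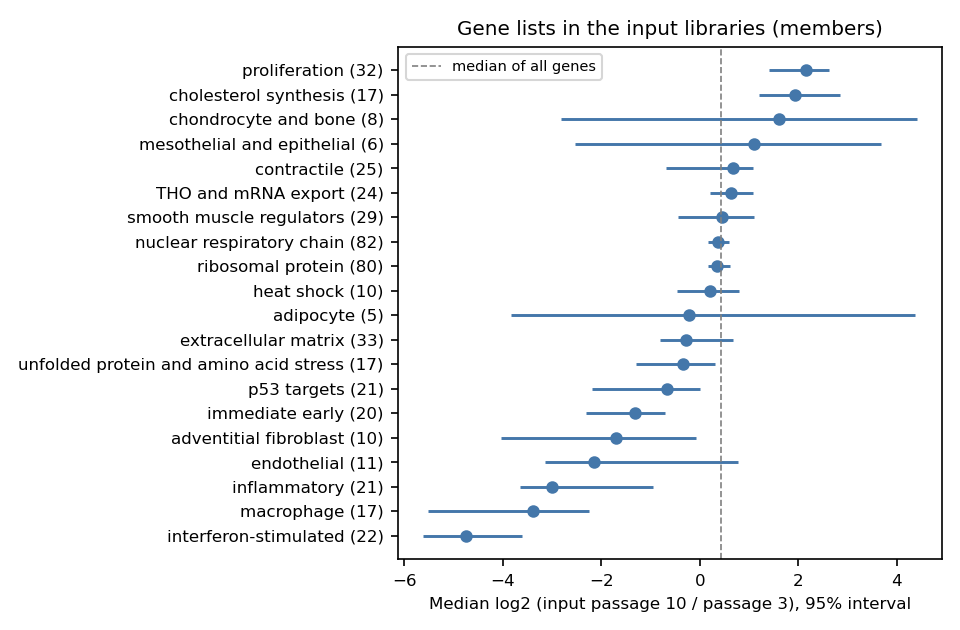
Median log2 ratio of passage 10 to passage 3 input CPM for each gene list, with the number of members in brackets and a line for the 95% interval of the median over its members, where genes unlisted in an input entered as 0 reads. The dashed line marks the median of all genes at 0.43, and the lists range from −4.75 for interferon-stimulated genes to 2.15 for proliferation genes.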

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

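Of the tests of the heart muscle pattern in this part, only that of skeletal muscle was chosen before its result was seen, and the others were chosen afterwards. Among the 48 genes named in RIP-seq, 18 pairs of gene and antibody lay on opposite sides of the input level at passage 3 and passage 10, beyond the counting interval at both. Those named genes include the 6 largest rises and 6 largest falls between passages for each antibody, and every flagged gene is among these. The count of pairs therefore follows in part from that choice, and the share over all genes was not computed. The difference between passages was not tested, because each passage had 1 library. With Thoc2 the log2 enrichment at passage 10 minus that at passage 3 was 3.485 for Cand2, 2.88 for Map3k12, 2.85 for Agbl5, 2.39 for Polr2b and 2.25 for Mylk. It was −3.14 for Tnnt2 and −1.77 for Echdc2. With Thoc5 it was 2.32 for Cand2, 1.76 for Map3k12, 1.97 for Agbl5, 1.47 for Polr2b and 1.66 for Mylk, and further 2.52 for Zbtb33 and 1.96 for Slc25a32. It was −5.66 for Malat1, −3.10 for Uba7, −2.94 for Echdc2 and −1.46 for Tnnt2 with Thoc5. The spans of Cand2, Map3k12, Agbl5, Polr2b, Mylk and Zbtb33 overlap those of other counted genes, so their differences may reflect reads of those genes. The median of the immediate early list with Thoc2 was −0.58 at passage 3 and 0.18 at passage 10, a difference of 0.76 (0.755), which was not tested either.

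Tnnt2 belongs to a wider pattern at passage 3, where heart muscle transcripts stood high in both immunoprecipitates. Of 17 heart genes listed after the pattern was noticed, 16 were enriched with Thoc2, with a median log2 enrichment of 3.91 (95% interval 3.08 to 4.82), and 13 with Thoc5, with a median of 2.004 (1.098 to 3.43) over the 14 listed there. With Thoc2, Myh6 reached 65.0 CPM, Mb 35.8 CPM and Actc1 and Myl2 27.2 CPM each, though the spans of Myh6, Mb and Myl2 overlap those of other genes. Binding by Thoc2 at both passages stays open: the median in the passage 10 Thoc2 immunoprecipitate was 0.372 over the 9 genes listed there (−0.69 to 1.099), but 8 were not listed, and 4 of the 9 stood under 1 CPM in the input, where the added 0.5 CPM shrinks a ratio. RNA of heart muscle may have entered the passage 3 immunoprecipitates: on a second list of 34 heart genes, tested with Thoc2, 6 of the 12 listed with under 1 CPM in the input reached a log2 enrichment of 2 (50.0%, exact interval 21.1% to 78.9%), against 9.54% of all such genes. This stays open, since over 50.0% had been required. The list without Casq2 and Ldb3, whose values had been seen and whose omission had been intended but was made only after the result was seen, gave 6 of 11 (54.5%, 23.4% to 83.3%). RNA of skeletal muscle stays open as well, because 0 of 3 such genes on a skeletal muscle list reached that level (0.0%, with an exact interval up to 70.8%), and the 25 listed members of the second heart list, apart from those 12, stood at 1 CPM or more in the VSMC input.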

How the results depend on the processing

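Alternatives on totals without ribosomal RNA, unlisted genes, list members and an omitted immunoprecipitate were chosen after seeing the data. Where a value below changed, the cause was not tested. The count of genes changed after Thoc5 silencing (0 by edgeR) was 47 by DESeq2, 1 with no low count filter and 0 to 47 when a library was left out. It stayed at 0 with limma-voom, other scaling factors, a minimum of 10 reads in each library and a test against a fold of 1.5. The Thoc5 log2 fold change (−2.51) passed the threshold at −2.51 by DESeq2 and −2.51 with no filter, and ranged from −2.72 to −2.35 over the omissions. The number of gene lists past the threshold (3) was 0 with an estimated correlation, 5 with no filter, 5 with library totals and 5 to 10 over the omissions. The 4 RIP-enriched sets did not pass under any alternative run.

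The replicate numbers of shNT and shThoc5 share only a number, since nothing in the labels ties them to a culture or day. With the number as a replicate block, edgeR called 511 genes (179 higher, 332 lower), which included the 47 of DESeq2, and Thoc5 had a log2 fold change of −2.50. In this fit 11 lists passed, the 3 that passed without the block and 8 more: immediate early (camera adjusted p = 0.00093), cholesterol synthesis (0.00664), proliferation (0.01004), contractile (0.0108), p53 targets (0.0114), adventitial fibroblast (0.0123), inflammatory (0.0279) and ribosomal protein (0.045). Same-numbered libraries had deviations that correlated at 0.635 across genes, and a first component with 61.3% of the variance separated the numbers, which each omission of a library leaves unequal between the groups. The respiratory chain list, with a median of 0.00976 in this fit, tested as higher there and as lower without the block.

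Omitting a library turned the direction of a list in 16 instances. Ranges of the list medians over the omissions were −0.49 to 0.13 (contractile), −0.77 to 1.00 (proliferation), −0.01295 to 0.22 (p53 targets), −0.03345 to 0.11 (THO and mRNA export), −0.02215 to 0.0936 (heat shock), −0.79 to 0.34 (cholesterol synthesis), −0.40 to 0.069 (chondrocyte and bone), −0.28 to 0.17 (macrophage), −2.51 to 0.11 (adipocyte) and −0.0152 to 0.0179 (respiratory chain). For the other lists they were −0.47 to −0.0478 (matrix), −0.37 to −0.0561 (endothelial), −0.28 to −0.17 (stress), −0.13 to −0.0479 (smooth muscle regulators), −0.15 to −0.0897 (interferon-stimulated), 0.081 to 0.35 (inflammatory), −0.0428 to 0.26 (immediate early), −0.96 to −0.0868 (adventitial fibroblast) and −0.15 to 0.0182 (ribosomal protein). Library totals gave the respiratory chain a median of 0.0613. The 21 genes that the rule takes besides Thoc5 kept their direction in each alternative run. Their selection made this likely, since for all 47 DESeq2 calls both silenced libraries lay on the same side of both shNT libraries. All 21 were called by DESeq2 and with the replicate block, and not in the other runs that kept every library.

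At an enrichment threshold of 1.5-fold the enriched genes numbered 3547 and 4757 at passage 3 and 2824 and 2213 at passage 10 (Thoc2, then Thoc5), and at 4-fold they numbered 709, 746, 261 and 25. Genes shared by both proteins were 2706 and 1715 (passages 3 and 10) at 1.5-fold and 325 and 18 at 4-fold. Genes shared by both passages were 2157 and 1596 (Thoc2, Thoc5) at 1.5-fold and 190 and 16 at 4-fold. Added amounts of 0.1 or 1 CPM, TMM factors, a minimum of 50 reads and totals without ribosomal RNA kept these counts within 1.5 times. Under alternatives 3 list medians of immunoprecipitates moved beyond their interval and 235 did not, against 4 and 76 for inputs and 17 and 160 for named RIP genes. Depth limits the passage 3 immunoprecipitates most, where 3 reads correspond to 0.556 CPM (Thoc2) and 0.502 CPM (Thoc5), against 0.184 and 0.32 CPM at passage 10.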

Other observations

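All tests in this part were chosen after the results were seen. Transcripts encoded by mitochondria were scarce in the immunoprecipitates. They made up 5.22% of the passage 3 input but 0.627% of the Thoc2 and 0.979% of the Thoc5 immunoprecipitate, and 2.24% of the passage 10 input but 0.506% and 0.748% of the immunoprecipitates. COX1 stood at 13660 CPM in the passage 3 input, 2065 CPM with Thoc2 and 3552 CPM with Thoc5. Nuclear long non-coding RNAs went the other way at passage 3, from 0.0228% of the input to 0.233% with Thoc2 and 0.285% with Thoc5. At passage 10 they made up 0.0433% of the input, 0.0786% with Thoc2 and 0.0415% with Thoc5. Within this class Firre was enriched in all 4 immunoprecipitates, at log2 values of 3.17 (Thoc2) and 4.26 (Thoc5) at passage 3 and 4.47 and 2.41 at passage 10. Neat1 was enriched with Thoc5 at passage 3 (2.23) and stood at −0.02 with Thoc2. The list of these RNAs was made after some of its values had been seen.

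Thoc2 and Thoc5 shared enriched long transcripts, which were most of the smaller list at both passages, but at passage 10 only 596 of the 1482 genes enriched with Thoc2. Gene length as the whole cause is argued against, since after removal of the length trend the enrichments of the 2 proteins still had a rank correlation of 0.7173 or more at both passages. Counting noise of the shared input as the whole cause is argued against as well, with a covariance 184.2 times (passage 3) and 47.35 times (passage 10) the simulated one. Spread of the input library beyond counting noise was not simulated, so the shared input itself stays open. Capture of long RNA that does not depend on the antibody may account for the pattern and cannot be told apart from binding by the THO complex, because 0 control immunoprecipitates were among the libraries. Joint binding by subunits of a single complex stays open, as untested.

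Lars2, which encodes a mitochondrial leucyl-tRNA synthetase, was among the most enriched transcripts with Thoc2 at passage 3. A candidate explanation is that reads of 28S ribosomal RNA were counted at Lars2, since its log2 enrichment was 5.61, 4.07, 0.26 and 1.59 in the 4 immunoprecipitates where that of 28S was 5.435, 3.98, 0.24 and 1.74. The largest difference was 0.171, and one over 1.5 in any immunoprecipitate would have argued against it. No biological explanation was tested.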
